A study of Mus musculus with 64 samples.

How the data were processed

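The study profiled cortex of C57BL/6J mice after unilateral injection of alpha-synuclein preformed fibrils (PFF) or PBS by bulk RNA-seq of nuclei that the labels describe as sorted for the neuronal antigen NeuN. The labels also give total RNA and tissue weights (13.6 to 57.1 mg). Mitochondrial and myelin transcripts, given below, argue against RNA from sorted neuronal nuclei alone. Per the labels' protocols, ribosomal RNA was depleted from 500 ng of total RNA, the RNA was sheared to about 300 bp, stranded libraries were made, and 75-bp single-end reads were sequenced. Per the submitters' processing notes, the authors used STAR 2.7, edgeR, limma and R 3.3.1 with the mouse build mm10 (GRCm38). The series describes a generalized linear model after control of unwanted variation, and the name of the deposited workbook gives 3 factors, TMM scaling and cage as a block. How those factors were made is not given in the sources used here.

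The deposited count files hold whole-number counts per gene for 1 library each, with 1 column for unstranded counting and 1 for each strand. The column with the most assigned reads was used, which held at least 16.4 times the other strand's counts, and the unstranded column was an alternative. Unmapped, multimapping, ambiguous and unassigned reads named no gene and stayed out of library sizes (68.8 to 73.1% of reads were in genes). The authors' deposited workbook holds log2 CPM per library, which equalled log2 CPM of the counts with TMM scaling to within 5e-14, and log2 fold changes, p-values and adjusted p-values of the authors' own comparisons. These were used only as the authors' values. Gene symbols, positions and biotypes came from the GENCODE M21 annotation of GRCm38, which held 54723 of the 54752 gene identifiers. Read alignment assigned reads to genes by the authors' settings, so values of near-identical copies such as Hspa1a and Hspa1b, of pseudogenes and of overlapping genes are uncertain.

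Groups came from the labels: sex, 1 or 3 months, PFF or PBS, and injected or non-injected hemisphere, with 4 mice each. Mice are named by cage and animal number (Q_0). PFF and PBS mice were in separate cages (5 and 4), so each comparison of the injections also compares cages. The 12 male libraries at 1 month that had been isolated in 2019 were the injected hemisphere of PBS mice and both hemispheres of PFF mice, and the design was chosen around this. All choices of groups, tests, gene lists, named genes and alternatives were fixed before the data were examined, except those named as chosen later. Among 96 pairs of replicates, the chi-square per degree of freedom of their counts was between 2.33 and 45.4, so no pair looked like the same library. Hemispheres pair by mouse because the labels give the same animal. Deviations of the 2 hemispheres from their group means correlated between -0.0474 and 0.328 across genes (median 0.16), and 26 of 32 mice correlated best with their own other hemisphere.

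Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and robust fits, and Benjamini-Hochberg adjustment over all genes tested, with 0.05 as the threshold. For PFF against PBS, 1 hemisphere per mouse entered the fit, with a mean for each combination of sex, month and injection and 3 factors of unwanted variation. The factors were the leading singular vectors of the residuals of log2 CPM (prior count 2) after a fit of sex and month alone, blind to the injection, and the contrast averaged the strata equally. The injected hemisphere had 32 libraries, and the non-injected one 24, without males at 1 month. Effects by month, by sex and within each stratum came from the same fit. Hemispheres were compared within mouse in 56 libraries of 28 mice, leaving out the 4 male PBS mice at 1 month whose hemispheres were isolated in different years, with factors blind to hemisphere. For 3 months against 1 month (females) and for females against males (3 months), counts of both hemispheres of a mouse were summed and no factors were used. Fold changes are those of the fit and so are adjusted for the factors, while CPM values are not.

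The 46 gene lists (cell type markers, neighbouring regions, pathways and stress responses) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes and also with an estimated correlation, and lists with at least 5 tested members were used. The named genes were, for each comparison, those past the threshold with a mean of at least 1 CPM, up to the 10 with the largest rise and the 10 with the largest fall, the 5 with the smallest p where fewer than 10 passed, the 3 leading members of each list that passed, and Snca. For the authors' deposited table they were the 5 smallest p-values in each direction. Cell markers, Lcn2 and the clock genes of the closing section were added after their values were seen.

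The tests were tested on simulated data with 200 changed genes in the real library sizes. With counts drawn around the fitted values, unwanted variation included, 76.1% of genes changed 1.25-fold and 92.5% of those changed 1.5-fold were recovered in the injected hemisphere (19436 genes, 6 of 19203 unchanged genes called). The shares were 68.7 and 73.1% in the non-injected hemisphere and 82.1 and 88.1% between hemispheres of PFF mice. Simulated counts for month and sex held 1 mean per gene and no unwanted variation. There 58.2 and 80.6% were recovered for month and 71.6 and 70.1% for sex. In a first version with 1 mean per gene and so no unwanted variation to find, the blind factors took up the simulated effect, and 0% of 1.25-fold and 1.5% of 1.5-fold changes were recovered in the injected hemisphere. The factors may therefore hide an effect that is the leading difference between samples, and fits without factors are given in the closing section.

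Alternatives were DESeq2 1.42.0 with the same design, its size factors in edgeR, no factors, factors from the residuals of the full model, nearly no filter (10 reads in all), the unstranded column, isolation date as a covariate, cage as a random block in limma-voom, counts summed per cage, leaving out each stratum and each mouse, and no pairing of the hemispheres. Leaving out mice with Ttr above 100 CPM in a library was added after the data were seen. In fits of a single hemisphere only libraries of that hemisphere counted for this, and in the other fits either library of a mouse did. Tables and plots used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.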

Results

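Preformed fibrils of alpha-synuclein (PFF), short aggregates that seed aggregation of the endogenous protein, or saline (PBS) were injected into 1 side of the brain of C57BL/6J mice. Bulk RNA-seq was made from the cortex of both hemispheres, from neuronal nuclei sorted by NeuN according to the labels. The 64 libraries came from 32 mice (16 PFF and 16 PBS), with 4 mice for each combination of sex, injection and time after injection (1 or 3 months). Each library held between 24172361 and 44436241 counts in genes (median 32538476). PFF and PBS mice shared none of the 9 cages. RNA of 12 of the 16 male libraries at 1 month was isolated in 2019, and RNA of the other 52 libraries in 2021.

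Neuronal transcripts were abundant in all 64 libraries. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was at 980 ± 73.7 CPM (SD, n = 64), and Rbfox3, which encodes the NeuN antigen named for sorting, was at 280 ± 19.3 CPM. Gad1, a GABA-synthesizing enzyme, was at 362 ± 28.1 CPM. Glial transcripts were present too: the myelin genes Mbp (1715 ± 260 CPM) and Plp1 (1555 ± 273 CPM) exceeded these neuronal markers. The labels name sorted nuclei but also total RNA and tissue weights. Mitochondrial mRNA, which lies outside the nucleus, made up 4.15 to 5.67% of gene counts in the 64 libraries. Together with the myelin transcripts, this argues against RNA from sorted neuronal nuclei alone. Every value below is of the mixed library. The astrocyte genes Aqp4 and Gfap were at 129 ± 13.4 and 94.7 ± 18.8 CPM, and microglial Cx3cr1 was at 44.8 ± 2.88 CPM. Xist, transcribed from the inactive X chromosome, lay between 736 and 1145 CPM in the 32 libraries labelled female and at or under 0.878 CPM in males. Y-linked Ddx3y lay between 78.6 and 97.7 CPM in males and at or under 0.292 CPM in females, so every sex label matched.

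Ttr, the thyroid hormone carrier made by choroid plexus epithelium, separated the libraries into 11 with 226 to 790 CPM and 53 with at most 26.2 CPM. The 11 libraries came from 11 mice, 6 PFF and 5 PBS, and were 6 injected and 5 non-injected hemispheres. The striatal receptor genes Drd1 (9.69 to 110 CPM) and Drd2 (0.492 to 73.3 CPM) also ranged widely between libraries.

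**Figure D1:**
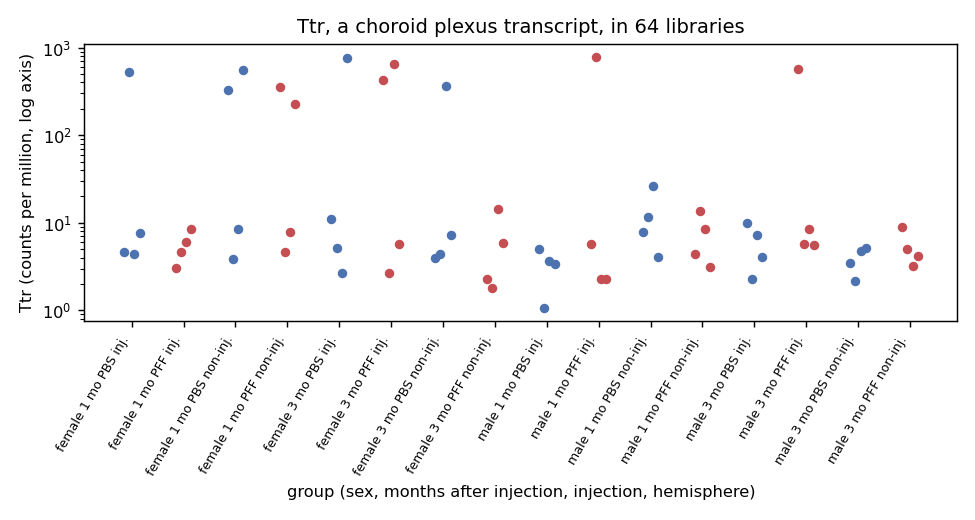
Ttr in CPM on a log axis for each of the 64 libraries (1 point per library, 4 per group, PBS blue and PFF red), by sex, months after injection, injection and hemisphere. In 11 libraries Ttr is between 226 and 790 CPM and in the other 53 it is at most 26.2 CPM.

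The first comparison asked how libraries of the injected hemisphere differed between PFF and PBS mice. Snca, the gene of alpha-synuclein (chromosome 6, 60731575 to 60829855, minus strand), was at 161 ± 11.7 CPM (SD) in 16 PFF mice and 156 ± 13.3 CPM in 16 PBS mice. Its log2 fold change was 0.05 with a standard error of 0.0364 (edgeR quasi-likelihood test, adjusted p = 0.813). The immediate early genes, which neurons transcribe after activity, were lower in PFF mice. Of the 30 measured, 29 had a log2 fold change below 0 and the median was -0.26 (camera, adjusted p = 3.81e-18, adjusted p = 0.266 with an estimated correlation). Among them, Ier5 differed by -0.21 ± 0.0451 (log2, SE), the neurotrophin gene Bdnf by -0.15 ± 0.0477 and the transcription factor gene Egr3 by -0.16 ± 0.052. None of the 30 passed over all genes, and 1 fell when adjusted over the list alone.

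Transcripts of glia were lower in the same comparison. The oligodendrocyte and myelin list was lower for all 17 members (median -0.12, adjusted p = 1.38e-12, adjusted p = 0.266 with an estimated correlation), of which 6 fell when adjusted over the list alone. These changes are adjusted for the factors. The mean log2 CPM of the list before that adjustment was lower in PFF mice in 3 of 4 strata and higher in males at 3 months (6.21 ± 0.0938 against 6.09 ± 0.179). The astrocyte list was lower for 16 of 17 (median -0.06, adjusted p = 6.13e-08, adjusted p = 0.266 with an estimated correlation), and 4 fell over the list alone. The astrocyte genes S100b and Ntsr2 were at 86.9 ± 6.57 against 93 ± 5.26 CPM and 66.1 ± 3.96 against 71.9 ± 6.25 CPM. The choroid plexus and ependyma list was higher (median 0.34, 12 of 16 members above 0, adjusted p = 0.000777, adjusted p = 0.266 with an estimated correlation), with Ttr at 155 ± 277 CPM in PFF and 84.9 ± 222 CPM in PBS mice. In all, 15 of the 46 lists passed with the preset correlation and none with an estimated correlation. Without the 6 mice whose injected-hemisphere library had Ttr above 100 CPM, an exclusion chosen after the data were seen, the immediate early list had an adjusted p of 0.626 and the choroid list 0.715. The immediate early list had an adjusted p of 0.749 without the male 1-month mice. Before adjustment for the factors its mean log2 CPM was lower in PFF mice in 4 of 4 strata, by less in males at 1 month (5.07 ± 0.134 against 5.22 ± 0.128) than in males at 3 months (4.46 ± 0.336 against 5.08 ± 0.433), so the lost call does not place the difference in the 1-month males. In non-injected hemispheres the immediate early list did not pass, but its mean was also lower in PFF mice in 4 of 4 strata. It was 4.63 ± 0.437 against 4.93 ± 0.38 (n = 16 each), so the difference was not particular to the injected side.

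The list of synuclein and Parkinson's disease genes did not pass (29 members, median log2 fold change 0.01, adjusted p = 0.301). Neither did the lists of microglia (adjusted p = 0.163), lysosome (adjusted p = 0.835), autophagy (adjusted p = 0.946), interferon response (adjusted p = 0.926) and cytokine and NF-kB genes (adjusted p = 0.707). With the preset correlation, related lists did pass: disease-associated microglia (0.0151), unfolded protein response (0.00971), proteasome and ubiquitin (0.0403) and oxidative stress (0.0403). Their adjusted p was 0.502 to 0.953 with an estimated correlation. Passing does not mean a rise, since of the 15 lists that passed 11 were lower and 4 higher in PFF mice. For single genes, edgeR called 0 of 19436, with 1475 at an unadjusted p under 0.05. DESeq2 called 2 and limma-voom with cage as a random block 0. Genes with the smallest p-values, each with an adjusted p of 0.259, included Sema6d, a guidance cue (log2 fold change -0.09, 85.6 ± 4.62 against 93.2 ± 11.4 CPM), and Pla2g7, a phospholipase gene (-0.12, 111 ± 7.22 against 120 ± 9.21 CPM). Both were lower in PFF mice in 4 of 4 strata of sex and month.

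**Figure D2:**
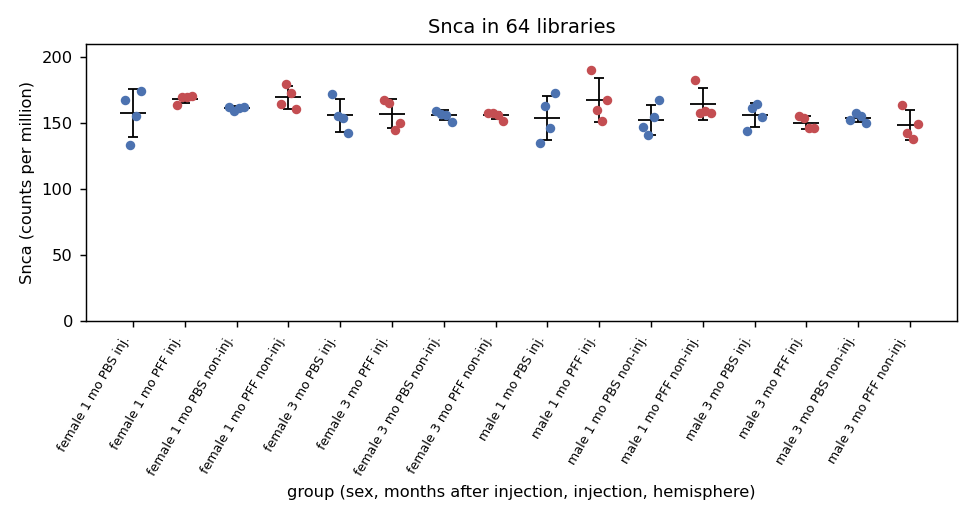
Snca in CPM for each of the 64 libraries (1 point per library, PBS blue and PFF red), with the mean and SD of each group of 4 in black, by sex, months after injection, injection and hemisphere. All libraries lie between 133 and 190 CPM, and the PFF and PBS groups overlap.

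Whether the PFF difference in the injected hemisphere depended on sex was tested as the female minus male difference of the PFF change. Genes of cholesterol synthesis and uptake had a higher PFF change in females, with 23 of the 24 measured above 0 and a median difference of 0.22 (camera, adjusted p = 3.14e-20). The adjusted p was 0.0936 with an estimated correlation, and 18 of the 24 rose when adjusted over the list alone. Ldlr, the receptor that takes up low-density lipoprotein (chromosome 9, 21723483 to 21749919, plus strand), was at 32.8 ± 5.07 against 23.9 ± 3.29 CPM in PFF and PBS females at 1 month (SD, n = 4 each). In males at 1 month it was at 25 ± 1.11 against 34.4 ± 1.14 CPM. At 3 months it was at 30.7 ± 2.24 against 27.7 ± 2.72 CPM in females and 26.7 ± 4.15 against 36.3 ± 7.2 CPM in males. The difference between sexes was 0.71 ± 0.129 for Ldlr (log2, SE; edgeR adjusted p = 0.0422) and 0.46 ± 0.0843 for Insig1, a sterol sensor of the endoplasmic reticulum (chromosome 5, 28071363 to 28078662, plus strand; adjusted p = 0.0419).

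Within the 1-month mice the cholesterol list rose in PFF females (median 0.17, 24 of 24 members, adjusted p = 3.94e-14) and fell in PFF males (median -0.19, 24 of 24 members, adjusted p = 6.07e-14). With an estimated correlation the adjusted p was 0.177 and 0.184. In these females 7 of 46 lists passed and 0 with an estimated correlation. Besides cholesterol they included choroid plexus and ependyma (adjusted p = 1.62e-05), thalamic neurons (2.25e-05) and oligodendrocytes and myelin (0.000215). At 3 months the list was higher in PFF females by less (median 0.05, 19 of 24 members above 0, adjusted p = 0.0287, adjusted p = 0.841 with an estimated correlation) and did not pass in males (median -0.03, 14 of 24 below 0, adjusted p = 0.324). These changes are adjusted for the factors. Before that adjustment the mean log2 CPM of the list was lower in PFF males at 3 months too (5.13 ± 0.0592 against 5.26 ± 0.128). In non-injected hemispheres it was likewise higher in PFF females and lower in PFF males at 1 and 3 months. The pattern was thus not particular to the injected side. In the test of the difference between sexes, 17 of 19436 genes passed, 4 with a higher and 13 with a lower PFF change in females. Besides Ldlr and Insig1, the higher ones were Rdh11, a retinol dehydrogenase gene (0.32 ± 0.0633), and Parn, a poly(A) ribonuclease gene (0.24 ± 0.0484). The lower ones were led by Maml3, a Notch coactivator (chromosome 3, 51685907 to 52105076, minus strand; -0.68 ± 0.104, adjusted p = 0.00324). They included the imprinted gene Peg10 (-0.61 ± 0.107), the adhesion gene Sdk2 (-0.56 ± 0.107), Pdzd2 (-0.37 ± 0.0553, adjusted p = 0.00319), the inositol transporter Slc5a3 (-0.37 ± 0.0774) and the potassium channel Kcnq2 (-0.18 ± 0.0387). Maml3 was at 14.5 ± 1.23 against 17.8 ± 3.91 CPM in PFF and PBS females at 1 month and 15.7 ± 2.11 against 10.3 ± 0.977 CPM in males.

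The voltage-gated ion channel list (median -0.07, adjusted p = 5.77e-05) and the unfolded protein response list (median -0.10, adjusted p = 0.00026) also had a lower PFF change in females. Their adjusted p was 0.467 and 0.383 with an estimated correlation. In all 16 of 46 lists passed, and 0 with an estimated correlation. Cell type lists among them were fibroblasts and meninges (adjusted p = 0.00444), hippocampal and olfactory neurons (0.0189), disease-associated microglia (0.0238) and striatal projection neurons (0.0372). The choroid plexus list had a higher PFF change in females in this fit (adjusted p = 0.0189, adjusted p = 0.467 with an estimated correlation) and a lower one without factors (adjusted p = 0.0019). DESeq2 called 125 genes, the fit without factors 5 and the fit without the mice with high Ttr 6. Maml3 and Pdzd2 passed whichever of the 32 mice was left out, and none of the other 15 genes did so in every such fit.

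**Figure D3:**
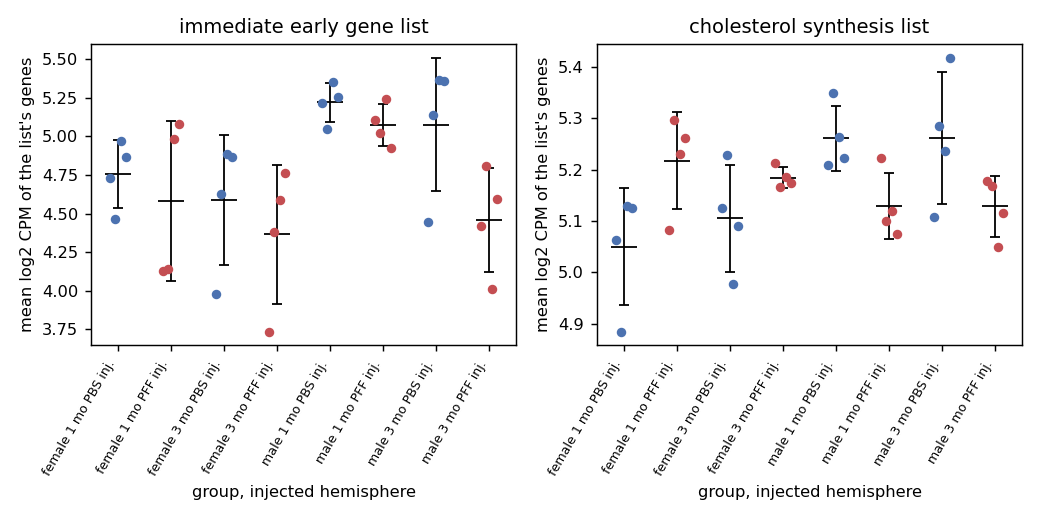
Mean log2 CPM of the members of the immediate early gene list and of the cholesterol synthesis list in each injected-hemisphere library (1 point per mouse, PBS blue and PFF red), with the mean and SD of each group of 4 in black. The cholesterol list averages 5.22 ± 0.0943 in PFF and 5.05 ± 0.115 in PBS females at 1 month, and 5.13 ± 0.0646 against 5.26 ± 0.063 in males, while immediate early genes vary widely between mice of a group.

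Whether the PFF difference changed between 1 and 3 months was tested in the same way. Markers of cortical layers 2 to 4 had a higher PFF change at 3 months, with all 11 members above 0 and a median of 0.15 (camera, adjusted p = 3.9e-06, adjusted p = 0.0104 with an estimated correlation). Of these, 3 rose when adjusted over the list alone. Leading members were Lamp5 (0.20 ± 0.0505, log2, SE), Rspo1 (0.32 ± 0.104) and Scnn1a, a sodium channel gene used as a layer 4 marker (0.92 ± 0.261). Scnn1a was at 1.97 ± 0.47 against 4.46 ± 1.95 CPM in PFF and PBS males at 1 month and 4.21 ± 0.322 against 3.02 ± 1.18 CPM at 3 months. Other lists of cell types also had a higher PFF change at 3 months: thalamic neurons (median 0.32, 9 of 11 members above 0, adjusted p = 0.000234), striatal projection neurons (0.21, 22 of 23, adjusted p = 0.000628), oligodendrocytes and myelin (0.10, 15 of 17, adjusted p = 0.0136) and neurons in general (0.05, 10 of 16, adjusted p = 0.0241). Each of these 4 had an adjusted p of 0.895 with an estimated correlation, and 9 of 46 lists passed in all. The unfolded protein response list had a lower PFF change at 3 months (median -0.04, adjusted p = 0.013, adjusted p = 0.895 with an estimated correlation), with the chaperone gene Hspa5 at -0.26 ± 0.084. No gene passed in edgeR, where 1283 had an unadjusted p under 0.05, and DESeq2 called 3. Tmem215 (0.49 ± 0.091, adjusted p = 0.111) and Gm765 (0.90 ± 0.175, adjusted p = 0.143) had 2 of the smallest p-values.

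Within single strata of 4 PFF against 4 PBS mice, males at 1 month had 8 genes past the threshold in edgeR. The count was 43 in DESeq2, 39 without factors, 290 with residual factors and 4 to 28 when 1 mouse was left out, and 2 of 35 splits of the mice, the real one included, gave at least 8. PFF males had more Slc5a3 (64.1 ± 4.4 against 42.3 ± 3.44 CPM, log2 fold change 0.53, adjusted p = 0.00372) and more Sh3rf3, a ubiquitin ligase gene (48.1 ± 2.47 against 34.9 ± 2.61 CPM, 0.38, adjusted p = 0.00372). Manf, a neurotrophic factor induced by endoplasmic reticulum stress, rose as well (50.2 ± 3.26 against 35.6 ± 1.98 CPM, 0.41, adjusted p = 0.014), as did Cwh43 (0.69) and Gm42549 (1.03). Opalin, a gene of myelinating oligodendrocytes, fell (16.5 ± 1.4 against 23.5 ± 1.07 CPM, -0.51, adjusted p = 0.03), as did Tmem215 (-0.61) and Gm765 (-1.33). The unfolded protein response list rose (adjusted p = 4.23e-06, adjusted p = 0.288 with an estimated correlation), and 9 of its 30 genes rose over the list alone. The layer 2 to 4 list fell (median -0.14, adjusted p = 3.03e-05, adjusted p = 0.0459 with an estimated correlation). So did the oxidative phosphorylation list (median -0.08, adjusted p = 1.54e-10, adjusted p = 0.522 with an estimated correlation) and the oligodendrocyte and myelin list (median -0.16, 16 of 17 members below 0, adjusted p = 1.59e-06, 0.522). The immediate early (median -0.39, 27 of 30, adjusted p = 4.05e-06), striatal (-0.22, 21 of 23, adjusted p = 0.00685), astrocyte (-0.07, 13 of 17, adjusted p = 0.00946) and general neuron lists (-0.05, 11 of 16, adjusted p = 0.0439) were lower as well, with adjusted p of 0.574 to 0.789 with an estimated correlation, and 16 of 46 lists passed in all.

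In females at 3 months 1 gene passed, Nptx2, a pentraxin secreted at excitatory synapses. It was at 22.4 ± 0.641 CPM in PFF and 32.1 ± 2.65 CPM in PBS mice (-0.56, edgeR adjusted p = 0.0013). Without factors its change was -0.52 with an adjusted p of 1. Females at 1 month and males at 3 months had 0 genes in edgeR, with 1302 and 1252 at an unadjusted p under 0.05, and DESeq2 called 0 and 7. Cage and injection cannot be told apart within a stratum. In males at 3 months most tissue pieces of PFF mice were also heavier by the labels, and weight was not modeled.

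In the non-injected hemisphere, 12 PFF and 12 PBS mice were compared. Males at 1 month were left out because their PFF and PBS libraries had been isolated in different years. Targets of the glucocorticoid receptor were higher in PFF mice, with 14 of 15 above 0 and a median of 0.23 (camera, adjusted p = 8.35e-11, adjusted p = 0.0209 with an estimated correlation). Tsc22d3, a glucocorticoid-induced leucine zipper gene, differed by 0.31 ± 0.0505 (log2, SE; adjusted p = 0.0434), Fkbp5 by 0.23 ± 0.0644 and the metallothionein Mt2 by 0.30 ± 0.082 after adjustment for the factors. Group means before that adjustment were closer, with Tsc22d3 at 60.3 ± 9.5 against 58.9 ± 9.2 CPM. The mean log2 CPM of the list was higher in PFF mice in 2 of 3 strata and lower in females at 3 months (3.75 ± 0.147 against 3.84 ± 0.211). The call ended without factors, where the list had an adjusted p of 0.871 and Tsc22d3 a log2 fold change of 0.04, with residual factors (0.603) and with counts summed per cage (0.983). The 3 factors held 32.9% of the injection label, where chance gives 14.3%. In injected hemispheres the glucocorticoid list did not pass. Its mean log2 CPM before adjustment for the factors was nevertheless higher in PFF mice there too, in 3 of 4 strata. It was 4.07 ± 0.274 against 3.88 ± 0.209 (n = 16 each), so the difference was not particular to the non-injected side.

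The endothelial list was lower in the non-injected hemisphere of PFF mice for 17 of 20 members (median -0.07, adjusted p = 6.22e-05, adjusted p = 0.32 with an estimated correlation). Of these, 2 passed over all genes, the receptor genes Kdr (-0.24 ± 0.0472) and Tek (-0.21 ± 0.0417), which kept the call in 5 and 3 of 14 alternatives. In total 8 of 19082 genes passed. Galnt15 (0.50) and Rhob (0.13) were higher. Cxxc5 (-0.13; 74.6 ± 2.94 against 82.8 ± 5.44 CPM), Lrig1 (-0.17) and Sox21 (-0.32; 7.38 ± 0.785 against 8.96 ± 1.04 CPM) were lower. Cxxc5 and Sox21 also passed without factors, with adjusted p of 0.00238 and 0.0471. Snca differed by 0.03 ± 0.0253 (adjusted p = 0.954). With isolation date as a covariate, with cage as a random block and with counts summed per cage 0 genes passed, against 8 in edgeR (1059 at an unadjusted p under 0.05) and 21 in DESeq2.

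The series names asymmetry after the injection, so both hemispheres were compared within each mouse. In the 16 PFF mice, markers of striatal projection neurons were higher in the injected hemisphere for 23 of 23 members (median 0.19, adjusted p = 1.32e-21, adjusted p = 0.225 with an estimated correlation). The dopamine receptor gene Drd2 was at 14.9 ± 4.75 against 10.7 ± 5.22 CPM and was higher in 13 of 16 mice. Drd1 was at 31.1 ± 6.12 against 25.5 ± 8.07 CPM, higher in 14 of 16 mice, and neither passed. Myelin genes were higher as well (median 0.07, 16 of 17 members, adjusted p = 9.4e-10, adjusted p = 0.284 with an estimated correlation). Meningeal fibroblast genes were lower (median -0.09, 15 of 15, adjusted p = 0.000656, adjusted p = 0.572 with an estimated correlation). PBS mice had the same 3 directions, with medians of 0.11 for the striatal list (adjusted p = 0.000193), 0.05 for the myelin list (adjusted p = 0.000193) and -0.19 for the fibroblast list (adjusted p = 2.43e-07). Each had an adjusted p = 0.711 with an estimated correlation. In PFF mice 12 of 46 lists passed in all, and 0 with an estimated correlation. Neuron lists among them were layers 2 to 4 (adjusted p = 0.00153), layers 5 and 6 (0.00251) and thalamic neurons (0.00848). In PBS mice 6 of 46 passed.

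For single genes, edgeR called 0 of 19826 between hemispheres in PBS mice (751 at an unadjusted p under 0.05) and 0 in PFF mice (1167). It also called 0 in the difference of the hemisphere effect between PFF and PBS mice (564), which is the direct test of asymmetry due to PFF. DESeq2 with the same factors called 0 in each. These factors held 26.6% of the hemisphere label, where chance gives 10.7%, so they may hide part of a hemisphere difference. Without factors 5 genes passed in PBS mice, 0 in PFF mice and 0 for the difference. In PFF mice the smallest p-values included those of N4bp3 (0.20 ± 0.0412, log2, SE, higher in 14 of 16 mice) and E2f1, a cell cycle transcription factor gene (0.14 ± 0.0309), with an adjusted p of 0.351. Snca was at 161 ± 11.8 CPM in the injected and 159 ± 11.6 CPM in the non-injected hemisphere of PFF mice. For the difference of the effect 4 of 46 lists passed: microglia (median -0.03), oxidative phosphorylation (-0.02), ribosomal protein (-0.02) and cholesterol synthesis (0.02). Each had an adjusted p of 0.0333 and an adjusted p = 0.993 with an estimated correlation. With 3 factors taken from the residuals of the full model the counts of genes were 867, 25 and 4.

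Between 1 and 3 months after injection, 8 against 8 female mice were compared with both hemispheres summed. By the labels, the tissue taken from a mouse, both hemispheres together, weighed more in every 3-month than in every 1-month female. What the size of the dissected pieces adds to the differences below was not tested. Chaperones of the endoplasmic reticulum fell. Hspa5 went from 300.3 ± 18.7 to 200 ± 8.8 CPM (log2 fold change -0.59, edgeR adjusted p = 5.44e-09), calreticulin (Calr) from 363 ± 8.89 to 282 ± 15.5 CPM (adjusted p = 4.42e-09) and Pdia6 from 91 ± 4.22 to 68.3 ± 3.08 CPM (adjusted p = 1.19e-08). Of 30 unfolded protein response genes, 18 fell and 1 rose (camera, adjusted p = 1.54e-11, adjusted p = 0.119 with an estimated correlation). Of 31 heat shock and chaperone genes 14 fell and none rose (adjusted p = 9.89e-08, adjusted p = 0.259 with an estimated correlation). The same 3-month females entered the comparison with males below. Clock-controlled genes went the other way. Dbp rose from 29.6 ± 4.66 to 56.4 ± 2.42 CPM (adjusted p = 1.05e-07), Ciart from 8.55 ± 2.17 to 17 ± 2.14 CPM, and Nr1d2 and Per3 by 0.41 and 0.39 on the log2 scale, while Arntl changed by -0.30. In the clock list 10 of 19 rose and 3 fell (adjusted p = 2.46e-06, adjusted p = 0.235 with an estimated correlation).

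Top2a, a topoisomerase gene of dividing cells, fell from 3.86 ± 0.642 to 1.91 ± 0.313 CPM between 1 and 3 months and Mki67 from 3.94 ± 0.494 to 2.16 ± 0.352 CPM. Olig2 and Gpr17 of oligodendrocyte precursors changed by -0.38 and -0.39 on the log2 scale. Of the 11 precursor genes 3 fell (adjusted p = 0.0045, adjusted p = 0.605 with an estimated correlation). Colq, the collagen tail of acetylcholinesterase, was at 0.866 ± 0.182 against 2.49 ± 0.685 CPM (-1.51), and Cdkn1a, a p53 target, at 11.6 ± 1.48 against 21.3 ± 4.84 CPM. Of the layer 2 to 4 genes 6 of 11 rose (adjusted p = 6.28e-05, adjusted p = 0.119 with an estimated correlation). Rorb went from 64.4 ± 6.41 to 97.1 ± 4.93 CPM and Cux1 from 91.3 ± 5.07 to 134 ± 8.47 CPM. The layer 5 and 6 list was lower (median -0.12, 12 of 15 members below 0, adjusted p = 0.00623, adjusted p = 0.119 with an estimated correlation), with Fezf2 at -0.31 and Crym at -0.44. The oligodendrocyte and myelin list was lower too (median -0.15, 16 of 17, adjusted p = 0.00188, adjusted p = 0.923 with an estimated correlation), and 14 of 45 lists passed in all. Gm765 had the largest rise among named genes (1.65; 16.2 ± 1.55 against 5.2 ± 1.69 CPM). Snca was at 156 ± 7 against 164 ± 8.99 CPM (adjusted p = 0.132). Snca, 3 months against 1 month, females, passed only when mouse P_1 was left out (-0.09, adjusted p = 0.0241). In total 3712 of 21010 genes passed, 1894 higher and 1818 lower at 3 months. Isolation dates of the groups overlapped on 1 day, and with the date as a covariate 84 genes passed. Rorb then changed by 0.54 instead of 0.59 (adjusted p = 0.146), Top2a by -0.93 instead of -1.01 (0.193) and Ciart by 0.68 instead of 1.01 (0.147), while Dbp (1.10), Cux1 (0.52) and Calr (-0.37) still passed. Olig2 shrank from -0.38 to -0.16 (0.625) and Cldn11 from -0.28 to -0.09 (0.913), and the oligodendrocyte and myelin list had an adjusted p of 0.956. On the shared day, V_3 was the only female at 1 month, with Q_0 and W_0 at 3 months. The date-adjusted changes thus rest on 1 mouse at 1 month and cannot tell genes that follow the date from genes that do not. The lower count does not settle whether the date made these changes.

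**Figure D4:**
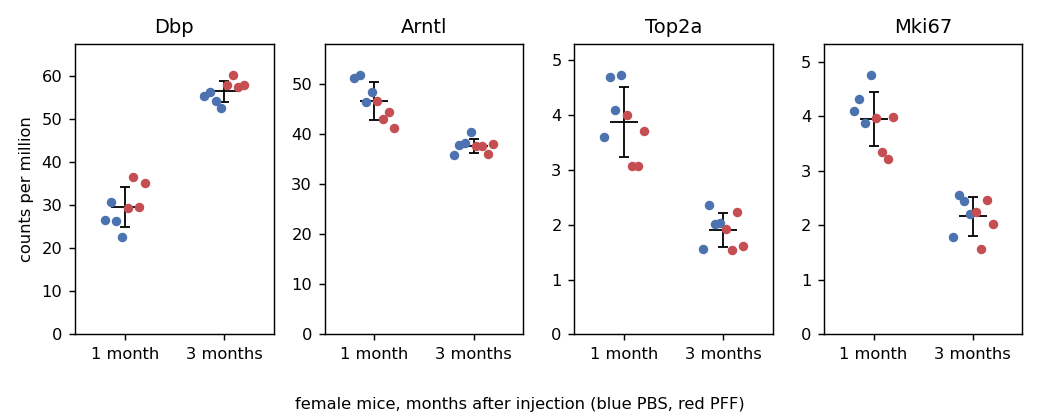
Dbp, Arntl, Top2a and Mki67 in CPM for each female mouse (1 point per mouse, both hemispheres summed, PBS blue and PFF red), with the mean and SD of 8 mice per time in black. Dbp is higher at 3 months (56.4 ± 2.42 against 29.6 ± 4.66 CPM), and Top2a and Mki67 are lower, with no overlap between the times in these 3 genes.

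At 3 months, 8 female and 8 male mice were compared. Xist was at 995 ± 71.1 against 0.177 ± 0.151 CPM, and Y-linked Ddx3y at 0.0837 ± 0.0772 against 89.6 ± 2.42 CPM. The X-linked translation factor Eif2s3x, which escapes X inactivation, was at 30.1 ± 0.846 against 19.5 ± 1.13 CPM. Heat shock genes were lower in females, with all 31 members below 0, of which 17 fell (adjusted p = 5.66e-21, adjusted p = 0.036 with an estimated correlation). Hspa1b, an inducible Hsp70 gene with a near-identical copy, was at 3.03 ± 0.338 against 6.48 ± 2.38 CPM (adjusted p = 0.00104) and Hsph1 at 345 ± 18.8 against 415 ± 30.1 CPM. Unfolded protein response genes were lower too (13 of 30 fell, adjusted p = 1.23e-16, adjusted p = 0.036 with an estimated correlation), led by Hyou1 (97.3 ± 2.16 against 119 ± 5.83 CPM). The same 8 females entered the comparison with 1 month, so the lower values there and here are not independent. In injected hemispheres of PBS mice the mean log2 CPM of this list was 5.135 ± 0.0497 in females at 3 months. It was 5.322 ± 0.0176 in females at 1 month, and 5.312 ± 0.0644 and 5.309 ± 0.0725 in males at 1 and 3 months. PFF females had 5.283 at 1 month and 5.101 at 3 months, and PFF males 5.459 and 5.286.

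Immediate early genes were lower in females for 28 of 30 (4 fell, adjusted p = 2.2e-07, adjusted p = 0.738 with an estimated correlation), with Egr3 at 162 ± 29.6 against 240 ± 32.2 CPM. The clock genes Dbp and Nr1d1 were higher by 0.52 and 0.41 on the log2 scale. Striatal genes (median 0.31, adjusted p = 1.89e-08) and choroid plexus genes (median 1.14, adjusted p = 0.0133) were higher in females, with an adjusted p of 0.733 and 0.816 with an estimated correlation. The lists of oligodendrocytes and myelin (adjusted p = 4.66e-06), fibroblasts and meninges (0.00767) and blood cells (0.003) passed as well. Their adjusted p was 0.459 to 0.816 with an estimated correlation, and 17 of 46 lists passed in all. Of the mice with high Ttr at 3 months 4 were female and 1 male, and without them the choroid plexus list was lower in females (adjusted p = 0.00177). In total 856 of 20903 genes passed, 438 higher and 418 lower in females. Without the mice with high Ttr, which leaves fewer mice, 106 passed. Females and males were housed in separate cages, and the tissue pieces of most females were heavier by the labels.

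In the authors' deposited table, which lists 16240 genes, 3564 passed an adjusted p of 0.05 between PBS and PFF over all libraries, 1750 higher in PBS and 1814 higher in PFF. By p-value its leading genes included Y-linked Uty, the Hedgehog receptor Ptch1 and Sema6d, higher in PBS, and the endophilin gene Sh3gl2, the iron-binding lipocalin Lcn2 and Arhgap26, higher in PFF. For Snca the authors' deposited table gave a PBS minus PFF value of -0.05 (adjusted p = 0.000545). Among mice in the injected hemisphere the PFF minus PBS log2 fold change was -0.09 for Sema6d (SE 0.0205), -0.11 for Ptch1 (SE 0.0288), 0.06 for Sh3gl2 (SE 0.0255) and 2.64 for Lcn2 (SE 1.59). Their adjusted p ran from 0.259 to 0.734. Of the 3563 genes of the authors' deposited table that were also tested over mice, 3423 (96.1%) had the same direction. That share is no independent support, since the 32 injected-hemisphere libraries of this fit are among the authors' 64. Of these 3563, 899 had an unadjusted p under 0.05.

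The authors' deposited table gave 9978 genes between 1 and 3 months, 8178 between males and females and 3368 between hemispheres. It gave 2450 and 1555 between PFF and PBS in the injected and non-injected hemisphere. The signs of these last comparisons run from PBS to PFF against their names. Across genes, their fold changes correlate with PFF minus PBS differences of mean log2 CPM at -0.964 and -0.953 (genes are not independent replicates).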

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

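The exclusion of mice with high Ttr, the limit of 100 CPM and the 3 tests of the Ttr pattern (choroid plexus tissue, a response of the whole mouse and PFF injection) were chosen after the Ttr values were seen, while the tests of differences between groups and the splits were chosen before.

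Ttr stood far from the other 3 libraries of its group in 5 libraries, by the gap to the nearest library divided by the range of the group. The libraries were male 1 month PFF injected, mouse I_3 (789.6 against 5.68 CPM, 0.996), male 3 months PFF injected, mouse J_1 (565 against 8.54 CPM, 0.995), and female 1 month PBS injected, mouse P_1 (529.8 against 7.61 CPM, 0.994). The other 2 were of females at 3 months with PBS, mouse Q_10 in the injected (758 against 10.9 CPM, 0.989) and mouse Q_3 in the non-injected hemisphere (366 against 7.18 CPM, 0.991). Over 4 measures in each of the 16 groups, 64 sets of 4 libraries in all, 9 sets had a library this far from the others (5 for Ttr, 2 for Snca and 2 for gene counts), where chance gives about 1 in 20.

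For the 11 libraries with Ttr above 100 CPM, a response of the whole mouse is argued against, since 0 of the 11 mice had both hemispheres above the limit. No effect of the PFF injection was seen, as 6 PFF and 5 PBS mice had such a library, a difference of 1 mouse (Fisher exact p = 1). So few mice cannot exclude such an effect. Choroid plexus tissue taken with the cortex may be the source: 10 of the 15 other markers, or 66.7%, including Kl (up to 72.9 CPM against at most 8.46 CPM in the other 53 libraries), Clic6, Aqp1 and Otx2, lay above all 53 others in the median such library. Each of these 10 did so in all 11 libraries, while Foxj1, Tmem212, Ccdc153, Dynlrb2 and Rarres2 did so in at most 3 of the 11. The labels name a sort for NeuN, which would remove such cells, but glial transcripts were abundant in all 64 libraries and local expression was not tested, so this stays open.

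Snca was far from its group in 2 libraries: male 1 month PFF non-injected, mouse I_0 (182.3 CPM, nearest 158.9 CPM, 0.952), and female 1 month PFF injected, mouse V_0 (164 CPM, nearest 169.5 CPM, 0.856). The Snca difference in the injected hemisphere stayed between 0.02 and 0.08 (log2) over all alternatives and left-out mice and passed in none. Gene counts were far from the group in mouse D_3, male 3 months PBS injected (24910000, nearest 31170000, 0.917), and in mouse P_1, female 1 month PBS non-injected (44440000, nearest 29680000, 0.993).

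The PFF change in the injected hemisphere differed between females and males for 17 genes, with Maml3 and Pdzd2 at the smallest adjusted p-values. Of 100 splits of the mice, 2 gave as many genes, the real one included, and the highest other gave 89. Chance in the choice of single mice is thus argued against, although a split with 89 genes points to a structure among the mice. The count was 17 with all mice and 2 to 42 when 1 of the 32 mice was left out. It stayed within 1.5 times only without C_10, D_0, D_3, I_3, J_1, K_3, P_1, V_0 or W_10, and was highest without J_0 (30) or Q_0 (42). Maml3 passed in all 7 alternatives that tested it, with adjusted p from 0.00224 to 0.035, and Pdzd2 in 7 of 8, with adjusted p from 1.81e-06 to 0.153 without factors. Cages differ between all 4 sex and injection groups, so a difference between cages cannot be told apart from sex, and no alternative for this result modeled cages.

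The cholesterol synthesis list differed in the same way (median difference 0.22, adjusted p = 3.14e-20). Its adjusted p ran from 2.54e-20 to 0.0936 over 8 alternatives, the highest being that with an estimated correlation, and was at most 2.33e-15 whichever mouse was left out, that value without P_1. Group means of its members in log2 CPM were higher in PFF than in PBS females at 1 month (5.22 ± 0.0943 against 5.05 ± 0.115) and 3 months (5.19 ± 0.0206 against 5.11 ± 0.104). They were lower in PFF than in PBS males (5.13 ± 0.0646 against 5.26 ± 0.063, and 5.13 ± 0.0592 against 5.26 ± 0.128). Non-injected hemispheres had the same directions. PFF against PBS females had 5.19 ± 0.123 against 5.116 ± 0.0464 at 1 month and 5.205 ± 0.021 against 5.12 ± 0.0812 at 3 months. Males had 5.08 ± 0.0662 against 5.248 ± 0.0556 at 1 month, isolated in different years, and 5.102 ± 0.0597 against 5.279 ± 0.106 at 3 months.

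The PFF change differed between 1 and 3 months for the list of cortical layers 2 to 4 (median difference 0.15, adjusted p = 3.9e-06). Its adjusted p ran from 3.69e-06 to 0.0104 over 8 alternatives and reached 0.00101 without mouse P_1, the highest of the 32 left out. The number of genes for this comparison was 0 in edgeR (1283 at an unadjusted p under 0.05, 3 in DESeq2), so splits (100 of 100 give at least 0) say nothing about chance here, and the highest other gave 32. The 1-month males were isolated in 2019 and the 3-month males in 2021.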

How the results depend on the processing

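All alternatives except the exclusion of mice with high Ttr were chosen before the data were examined. Snca kept its direction and did not pass in any alternative of the injected comparison. Among values of named genes under an alternative or a left-out mouse, 1289 of 1386 kept their side of the threshold for month, 877 of 966 for sex, 331 of 639 for the PFF effect by sex and 139 of 342 for the non-injected hemisphere, and no gene past the threshold changed direction. Snca, which did not pass, changed sign in some of them, with log2 fold changes from -0.07 to 0.06 in the non-injected hemisphere and -0.07 to 0.03 by sex. In the injected hemisphere the myelin and astrocyte lists passed in 12 of 13 alternatives (highest adjusted p 0.266), the immediate early list in 10 (7.7e-36 to 0.749) and the choroid plexus list in 6 (2.21e-07 to 0.715). The glucocorticoid list of the non-injected hemisphere passed in 10 of 13 (2.5e-12 to 0.983, the highest with counts summed per cage). With an estimated correlation 6 lists passed over all comparisons instead of 141, and between 132 and 147 when a mouse was left out. For each count below that moved, the cause was not tested, unless fewer mice entered.

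Numbers of genes that moved by over 1.5 times are given by setting. DESeq2 called 2 in the injected and 21 in the non-injected hemisphere, 3 by month, 125 by sex, 3 in females at 3 months, 43 in males at 1 month and 7 in males at 3 months. With residual factors 21 passed in the injected and 501 in the non-injected hemisphere, 867 and 25 between hemispheres of PBS and PFF mice, 4 for their difference, 120 by sex, and 176, 0, 290 and 27 in females at 1 and 3 and males at 1 and 3 months. Without factors 5 passed between hemispheres of PBS mice, 5 by sex, 0 in females at 3 months (Nptx2 -0.52, adjusted p = 1), 39 in males at 1 month and 4 in males at 3 months. With nearly no filter 50 passed by sex, 0 in females at 3 months, 47 in males at 1 month and 4 in males at 3 months. In the unstranded column 0 passed in females at 3 months and 99 in males at 1 month. With isolation date as a covariate 0 passed in the non-injected hemisphere, 4 by sex, 2 in females at 3 months and 84 for month. For the non-injected hemisphere 0 passed with cage as a random block, 0 with counts summed per cage, 0 without females at 1 month, 2 without females at 3 months, 5 without males at 3 months and 3 with the male 1-month mice. Without males at 3 months 2 passed in the injected hemisphere. Without mice with high Ttr 6 passed by sex, 3 in males at 3 months and 106 for sex.

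Some lists reversed. In the non-injected hemisphere the striatal list fell without males at 3 months (adjusted p = 1.06e-13) and without females at 1 month (0.0167). The choroid plexus list reversed by sex without factors (0.0019) and with residual factors (1.83e-11), in females at 1 month with residual factors (0.000259), and for sex without mice with high Ttr (0.00177). The striatal list in males at 3 months reversed without mouse D_1 (5.95e-06), with adjusted p from 7.49e-14 without D_0 to 0.55 without J_1.

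Leaving out 1 mouse gave 0 to 1 genes in the injected hemisphere (1 without D_0 or P_10), 0 to 12 in the non-injected (within 1.5 times of 8 only without D_1, D_10, J_3, P_3, V_0 or V_10), 0 to 2 by month (1 without C_10, D_0, D_10 or I_0, 2 without I_10 or P_10) and 2 to 42 by sex. It gave 0 to 0 between hemispheres of PBS mice, 0 to 1 of PFF mice (1 without W_10) and 0 to 0 for their difference, with dispersion trends kept from all mice. Females at 1 month had 0 to 1 (1 without C_10), females at 3 months 1 to 4 (3 without D_10, 2 without P_1, Q_1 or V_3, 4 without W_3), males at 1 month 4 to 28 (4 without C_1, 5 without C_3, D_3, I_10, W_1 or W_3, 14 without D_10, J_1 or Q_10, 15 without I_0 or V_0, 16 without V_10, 28 without D_1) and males at 3 months 0 to 5 (above 0 without D_0, D_1, D_3, D_10, I_0, I_10, J_1, V_0, V_10, W_0, W_1, W_3 or W_10). Month gave 3069 to 4105, and female against male, 3 months, gave 497 to 1207 (518 without D_3, 497 without J_3, 507 without Q_1, 541 without Q_3, 544 without W_1). Without the mouse block, 0, 0 and 0 genes passed for the 3 hemisphere results in edgeR. Not run were leaving out a stratum for month, sex and the PFF effects by month and by sex, the date for hemispheres, and cages for any result but PFF against PBS in each hemisphere. Genes under about 1 CPM rest on few counts at this depth.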

Other observations

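The summaries of Lcn2 and Hspa1b by group, the fits with factors from deviance residuals and the test of the clock phase were chosen after results were seen, and the other tests of this part were chosen before.

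Lcn2, an acute-phase lipocalin, was higher in both hemispheres of some PFF groups. In females at 1 month it was at 1.95 ± 1.68 CPM in the injected and 1.77 ± 1.52 CPM in the non-injected hemisphere of PFF mice (SD, n = 4 each), against 0.0916 ± 0.0865 and 0.0337 ± 0.0389 CPM in PBS mice. In males at 3 months it was at 3.93 ± 2.27 and 4.23 ± 2.58 CPM in PFF and 0.648 ± 0.63 and 0.449 ± 0.43 CPM in PBS mice, while all 4 groups of females at 3 months had means of at most 0.062 CPM. The difference in the injected hemisphere did not pass (edgeR, log2 fold change 2.64, SE 1.59, adjusted p = 0.734). Hspa1b was at 11 ± 2.15 CPM in the injected and 11.2 ± 1.66 CPM in the non-injected hemisphere of PFF males at 1 month and at 4.57 ± 0.997 and 4.23 ± 0.75 CPM in PBS males. The reverse was measured at 3 months, with 4.97 and 5.08 CPM in PFF and 7.92 and 7.97 CPM in PBS males.

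The authors' deposited table calls 3564 genes between PBS and PFF, and no fit run here reached that number. With each library as a replicate 101 genes passed, against 23 with the mouse as a random block, a ratio of 4.39, and 0 with cage as a random block (1332 at an unadjusted p under 0.05), so hemispheres counted as separate replicates alone are argued against. Factors taken from the residuals of the full model gave 409 genes (22 with cage as a block) and factors from deviance residuals 823 (132 with cage as a block). With the former the median over 100 splits of whole mice was 16 genes, under the limit set beforehand, against 0 without factors. That median decides nothing about such factors, because single splits gave far more genes and how the authors made their factors is not given. A difference between PFF and PBS mice may contribute, but 18 of the 100 splits gave at least 409 genes, up to 1661, which points to a structure among the mice. The bound set beforehand for that test was met but was wrong, because a count that other splits reach excludes no difference, and cage cannot be told apart from injection.

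For the 3712 genes between 1 and 3 months in females, chance in the choice of mice is argued against, since 1 of 100 splits, the real one, gave as many and the highest other gave 849. A different clock phase at death fits for the clock genes alone: Arntl, Npas2 and Clock had a median log2 fold change of -0.239 against 0.392 for the 9 genes that peak with Dbp, and killing times are not in the labels. A handling difference of the female cages cannot be told apart from a change with time in females, and the latter stays open, as untested. In PBS males (non-injected hemisphere, all isolated in 2021) 47.7% of the genes kept the female sign, where the highest of the other 34 splits of those males gave 73.9%. That test, planned beforehand and voided after its value was seen, decides nothing, because isolation dates of those males also ran from earlier at 1 month to later at 3 months and killing days are not in the labels.

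Splits of the same mice say nothing about chance where the real count is 0, since each of the 100 splits gives at least that. This was so in the injected hemisphere (0 in edgeR, 1475 at an unadjusted p under 0.05, 2 in DESeq2), where the highest other split gave 41. It was also so for hemispheres of PBS mice (highest other 76), of PFF mice (479) and for their difference (21), with 0 in edgeR, 751, 1167 and 564 genes at an unadjusted p under 0.05 and 0 in DESeq2. A split with 479 genes points to a structure of the samples. For the non-injected hemisphere 2 of 100 splits gave at least 8 genes, up to 178, and for sex 1 of 100 gave 856, the highest other giving 19. Chance in the choice of single mice is argued against in both. The splits were drawn over single mice and not cages, so they say nothing about chance differences between cages. The 8 genes of the non-injected hemisphere nevertheless went to 0 with cage or date in the model.

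Within strata, each with 35 splits, the same holds for the 0 genes of females at 1 month in edgeR (1302 at an unadjusted p under 0.05, 0 in DESeq2, highest other 2) and of males at 3 months (1252, 7 in DESeq2, highest other 2). For males at 1 month 2 of 35 gave at least 8 genes, up to 18, so chance cannot be excluded for that count. For the 1 gene of females at 3 months, Nptx2, 1 of 35 splits gave as many, the real one, and the highest other gave 0. Nptx2 passed in 4 of 8 alternatives, with adjusted p from 1.22e-07 to 1 without factors, and whichever mouse was left out.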
